A study of Mus musculus with 18 samples.

How the data were processed

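The series holds 18 mouse RNA-seq libraries from 2 tissues, retina and RPE/choroid, at the age of 30 days. The mice were wild type, were Abca4 knockouts or were homozygous for the knock-in allele Abca4 L541P;A1038V, with 3 libraries per genotype and tissue. Per the labels, tissue was taken between 3 and 5 PM from mice of mixed 129SV and C57BL/6 background, and libraries were made with a stranded total RNA kit after removal of ribosomal RNA and read as 100 bp pairs on an Illumina HiSeq instrument. The sources used here do not say whether the counting used the strand or whether the 3 libraries of a group came from separate animals. Nor do they say whether retina and RPE/choroid of a number share a mouse, which sex excludes for some.

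Per the submitters' processing notes, reads were mapped to the mm9 assembly with TopHat and Bowtie2 and quantified with Cufflinks. The versions and the annotation are not given in the sources used here. The reference files at hand are of a later assembly, and from them only gene names were used, so positions are the ones in the deposited tables.

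The deposited gene tables list, per library, the fragments of each gene before scaling. The values are expected counts per the file headers and the values themselves: 98.5% of the retinal and 98.4% of the RPE/choroid values are whole numbers, and the others were rounded to the nearest whole number. The same deposited tables give FPKM per library, and a further pair of deposited tables gives 1 FPKM per genotype. Both are FPKM per the file headers. The authors' comparison tables give a p-value and a q-value per gene, also per the file headers. The fold change column of the authors' comparison tables was damaged by spreadsheet software, so directions for these tables were taken from the genotype FPKM. The deposited transcript tables give a transcript length in bases, per the file headers, which was used only to check the FPKM.

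The tables hold 22558 genes. In each tissue, 25 gene names had been turned into dates by spreadsheet software and 24 of them could be restored. The tables number the libraries of a genotype 0 to 2 while the labels number them 1 to 3, and nothing links the numbers, so libraries are named here by genotype and by the number of the table. The tables mark 10 gene estimates in single retinal libraries and 3 in single RPE/choroid libraries as failed. No columns of other samples were found, and among the 18 pairs of libraries of 1 group no pair was a copy, with r from 0.966 to 0.995 and a chi-square per gene from 3.39 to 99.8.

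Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood with robust estimation, TMM scaling, filterByExpr). The 9 libraries of each tissue were fitted together, and the 3 genotypes were compared in pairs. P-values were adjusted by the Benjamini-Hochberg method per comparison, and genes under 0.05 were called. The biological coefficient of variation was 0.114 in retina and 0.154 in RPE/choroid. Differences in genotype effect between tissues were tested as an interaction in a fit of all 18 libraries.

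The groups, the tests, 39 gene lists (RPE, retinal and other cell types, stress, immune, metabolic and signalling genes) and the alternatives were fixed before the data were examined. Lists with at least 5 measured members were tested with camera of limma 3.58.1 at its preset correlation of 0.01, and p-values were adjusted over the lists of a comparison. Camera with an estimated correlation between genes and fry were run as alternatives. Members were also counted one by one, first with p-values adjusted over all genes and then over the list alone. The list of mitochondrially encoded genes had no tested member. P-values of genes and lists in the text are these adjusted values unless another test is named, and every value with a plus-minus sign is a mean and SD of 3 libraries.

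Genes named in the text follow a rule fixed with the tests. They are Abca4, then the 10 largest rises and 10 largest falls among called genes whose groups do not overlap and whose mean FPKM is at least 1 in a group, then up to 4 called members of each list, or up to 2 members with the smallest p where none was called. The largest rises and falls leave out genes of small RNAs, symbols of the Rik, Gm, LOC and -ps kind and sex-linked genes. Of all genes that this rule picks, 1 is not reported here.

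The models were tested on simulated data made from these libraries, with 200 genes changed in knockout libraries. For knockout against wild type in retina, 70.1%, 94.0% and 97.0% of genes changed 1.5-fold, 2-fold and 4-fold were found, and 17 of 191 calls among 14604 genes were false. For knockout against wild type in RPE/choroid the shares were 41.8%, 74.6% and 95.5%, and 6 of 147 calls among 15390 genes were false.

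Alternatives were DESeq2 1.42.0, RLE scaling, limma on log2(FPKM + 1) and on log2(FPKM + 0.1), glmTreat against 1.5-fold, no expression filter, a filter at a mean FPKM of 1, a fit of the compared pair of groups only, the table number as a block, each library left out in turn, and a fit without genes within 10 Mb of Abca4. Terms for sex, for lens content and for rod content, fits without knockout libraries 0 and 2 in retina, without wild-type library 2 in RPE/choroid and without genes of other tissues were added after the results were seen. Other steps used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.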

Results

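Retina and RPE/choroid were compared between Abca4 knockout, knock-in and wild-type mice at the age of 30 days, with 3 libraries per genotype and tissue. Libraries held 11.6 to 23.6 M assigned fragments in retina and 14.6 to 30.0 M in RPE/choroid. Abca4 encodes the flippase that clears retinoid adducts from photoreceptor discs, and the knock-in protein carries a pair of substitutions known to impair its folding. The labels do not say that the 3 libraries of a group come from separate animals, so the p-values measure the spread between these samples. By Xist and Ddx3y, 2 wild-type, 1 knockout and 0 knock-in retinal libraries were male. In RPE/choroid every library was male except 1 of knock-in, so groups with both sexes hold more than 1 animal. By table number, knock-in 0 and 1, knockout 1 and 2 and wild-type 2 were female in retina and male in RPE/choroid, thus from different mice.

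Abca4 itself fell in knockout retina to 31% of wild type and stood at 80.4% in knock-in retina. Its level was 254 ± 27.4 FPKM in wild-type, 78.7 ± 4.19 in knockout and 204 ± 25.8 in knock-in retina. The knockout change was log2 -1.68 (SE 0.081, adjusted p = 4.32e-08). The knock-in change was log2 -0.30 (adjusted p = 0.186), with overlapping groups, and it reached the threshold with DESeq2 (adjusted p = 0.0323), with the table number as a block (0.0432) and without knock-in library 0 (0.0409). Knock-in exceeded knockout by log2 1.38 (adjusted p = 5.54e-07). In the authors' deposited comparison, q was 0.00293 for knockout and 0.886 for knock-in against wild type in retina. Fragments over the whole gene were counted, so the part of the transcript that knockout retina keeps is not given here.

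In RPE/choroid, Abca4 was lower overall. The knockout effects of the tissues differed by log2 0.90 (SE 0.203), which did not pass as an interaction (adjusted p = 0.0985). The level was 44.4 ± 13.1 FPKM in wild-type, 26.1 ± 0.49 in knockout and 38.6 ± 3.37 in knock-in RPE/choroid. The knockout change was log2 -0.79 (58.8% of wild type, adjusted p = 0.102), although each knockout library lay under each wild-type library. Wild-type library 2, which also carried the most rod transcripts, stood at 59.5 FPKM, and without it the fall reached the threshold (log2 -0.53, adjusted p = 0.00512). The knock-in change was log2 -0.23 (adjusted p = 0.888), and 0.02 without wild-type library 2 (adjusted p = 0.967). Knock-in lay above knockout by log2 0.56, which did not pass (adjusted p = 0.246) but did with DESeq2 (0.0345), a rod term (0.00208), the compared libraries alone (0.00345) and without wild-type library 2 in the fit (0.00246). The authors' deposited comparison gives q = 0.00347 for knockout and 0.869 for knock-in against wild type in RPE/choroid.

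**Figure D1:**
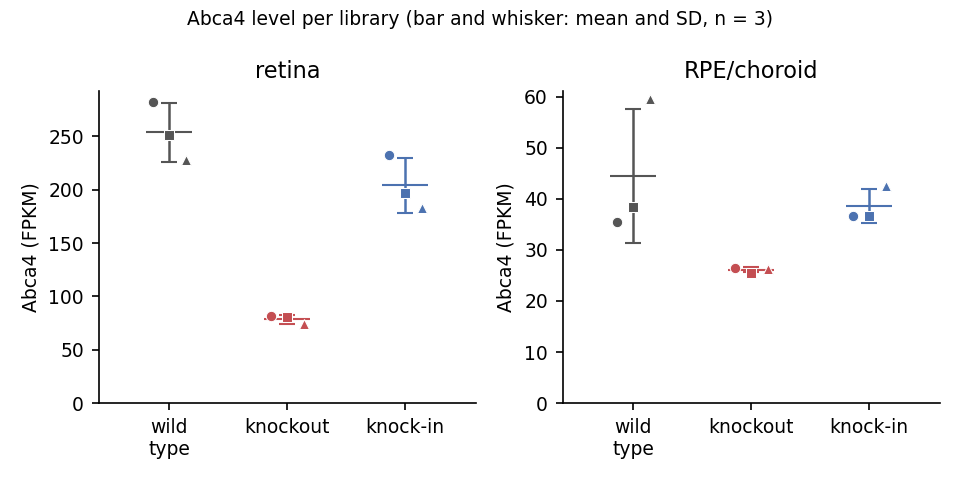
Abca4 in FPKM (vertical axis) per library (points) with mean and SD (bars and whiskers) for 3 libraries per genotype in retina and RPE/choroid. Knockout retina stands at 78.7 FPKM against 254 in wild type.

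Knockout retina differed from wild type in 144 of 14699 tested genes, 71 higher and 73 lower in knockout. Single changes included rises of the nuclear receptor Ppara and of Fgf2 and falls of Kif27, Wdr63 and Foxj1. By camera, genes of the RPE and of the retinal stress response were higher and immediate early genes lower, and of these 3 lists RPE markers alone also passed with an estimated correlation (adjusted p = 0.00587, against 0.133 and 0.313). Of the 144 genes, 46 changed at least 2-fold, and 1839 genes had an unadjusted p under 0.05 where 735 are expected by chance. The count was 253 without knockout library 0, 59 without knockout 1, 82 without knockout 2, 60 without wild-type 0 and 53 without wild-type 1. The authors' deposited comparison calls 474 genes (353 upward, 121 downward), and the 106 genes called by both tests have the same direction.

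Ppara, a receptor that controls fatty acid oxidation, rose in knockout retina from 0.134 ± 0.0182 to 2.74 ± 0.218 FPKM (log2 4.32, SE 0.159, adjusted p = 2.29e-09). Fgf2, a survival factor for photoreceptors, rose from 2.67 ± 0.54 to 10.8 ± 3.01 FPKM (log2 2.07, adjusted p = 8.79e-04), together with Nudt6, which lies beside it on the opposite strand and may share its reads (log2 1.56, adjusted p = 0.00224). Tc2n (log2 4.57, adjusted p = 5.35e-04) and the intraflagellar transport gene Ift57 (4.98 ± 0.386 to 14.4 ± 0.347 FPKM, log2 1.51, adjusted p = 1.59e-04) also rose. Among the largest falls were the kinesin gene Kif27 (log2 -1.66, adjusted p = 3.40e-05), the histamine-forming enzyme Hdc (log2 -1.59, adjusted p = 0.00295), the axonemal gene Wdr63 (log2 -1.502, adjusted p = 0.00222), Foxj1, a transcription factor of motile cilia (3.05 ± 0.823 to 1.16 ± 0.411 FPKM, log2 -1.37, adjusted p = 0.00175), Pla2g4b (log2 -1.25, adjusted p = 0.00175) and Ttc21a (log2 -1.25, adjusted p = 0.00421). These genes kept their calls without each single library, and Ttc21a lost its call when a term for lens content was added after the results were seen (log2 -1.222, SE at 132% of its value without the term, adjusted p = 0.0543).

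Other large changes in knockout retina lost their calls in some fits with 1 library fewer. Over the named genes of this comparison that did so, log2 with each library left out lay between 70.3% and 129% of the reported value. Pttg1, which encodes securin, rose from 0.758 ± 0.247 to 20.4 ± 11.4 FPKM (log2 4.6, adjusted p = 0.0101), lost without wild-type library 0, 1 or 2 (highest p 0.0811). Cldn1 rose by log2 1.78 (adjusted p = 0.0403) and lost its call without knockout 1 or 2 or any wild-type library (highest 0.183). Oca2 rose by log2 1.54 (adjusted p = 0.0133) and lost its call without knockout 1 or wild-type 0 or 1 (highest 0.0861). Cd59a, which protects cells from complement, fell from 35.2 ± 2.89 to 12.5 ± 1.71 FPKM (log2 -1.55, adjusted p = 0.0352) but lost its call without any 1 of the 6 libraries (highest 0.169) and with a term for sex (log2 -1.585, adjusted p = 0.0954). Tnfaip6 (log2 -1.44) lost its call without knockout 1 or 2 or any wild-type library (highest 0.169) and with the sex term (log2 -1.359, adjusted p = 0.0538). Jmjd7 (log2 -1.48), which overlaps Pla2g4b, lost its call without knockout 1 or wild-type 0 or 1 (highest 0.0935), and Alas2 (log2 -1.23) without knockout 1 or 2 or wild-type 0 or 2 (highest 0.112). With a term for lens content Cldn1, Oca2, Cd59a, Tnfaip6 and Alas2 were no longer called, with log2 at 67.5% to 113% and SE at 102% to 130% of those without it.

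RPE genes were higher in knockout retina. Of 21 measured RPE markers, 4 rose, 0 fell and 17 did not pass the threshold, and adjusted over the list alone 10 rose (median log2 0.865, camera adjusted p = 1.35e-19, adjusted p = 0.00587 with an estimated correlation). This list passed with each library left out. Rpe65, the isomerase of the visual cycle, rose from 2.99 ± 0.493 to 8.47 ± 2.13 FPKM (log2 1.48, adjusted p = 0.00222) and kept its call without each library. Rgr rose by log2 1.44 (adjusted p = 0.0178), lost without wild-type 0, 1 or 2 (highest 0.127). Lrat rose by log2 1.12 (adjusted p = 0.0288), lost without knockout 1 or any wild-type library (highest 0.144). Slc6a20a rose by log2 1.16 (adjusted p = 0.0238), lost without knockout 1 or any wild-type library (highest 0.0941).

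Pigment cell genes followed the RPE markers, with 2 of 13 risen, 0 fallen and 11 not past the threshold, or 6 risen and 1 fallen adjusted over the list alone (median log2 0.73, camera adjusted p = 5.58e-08, adjusted p = 0.133 with an estimated correlation). The retinoid cycle without Abca4 was higher as a group, with 3 of 17 risen (Rpe65, Rgr, Lrat), 0 fallen and 14 not past the threshold, but adjusted over the list alone 5 rose and 4 fell (median log2 0.16, camera adjusted p = 1.70e-04, adjusted p = 0.313 with an estimated correlation). Matrix genes of the choroid and Bruch membrane were higher (1 of 22 risen, 0 fallen, 21 not past, median log2 0.41, camera adjusted p = 1.15e-06, adjusted p = 0.313 with an estimated correlation). Their called member Col8a2 (log2 1.02, adjusted p = 0.0428) lost its call without any knockout library or wild-type 0 or 1 (highest 0.211) and with the sex term (log2 1.019, adjusted p = 0.0588). Lens genes were higher by a median log2 of 4.2 with 0 of 18 called (camera adjusted p = 1.99e-10, adjusted p = 0.313 with an estimated correlation), but not in every library: their median level was 2.66 and 3.94 in knockout 1 and 2 and -0.843 in knockout 0, under wild-type 0 (-0.207).

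Genes of retinal stress and gliosis were higher in knockout retina, in 14 of 15 members. Fgf2 rose, 0 fell and 14 did not pass the threshold, and adjusted over the list alone 3 rose (median log2 0.53, camera adjusted p = 6.47e-08, adjusted p = 0.133 with an estimated correlation). Knockout 0 showed the largest rise of the list, and without it the group still passed (adjusted p = 8.50e-04). Gfap, picked after its values were seen, was 32.1, 18 and 14.6 FPKM in knockout and 26.5, 22.4 and 23.5 in wild-type retina. Genes of microglia and macrophages were higher with 0 of 18 called (median log2 0.43, camera adjusted p = 6.73e-04, adjusted p = 0.313 with an estimated correlation). Müller glia and astrocyte genes had 1 of 15 risen, 0 fallen and 14 not past, or 3 and 1 over the list alone (median log2 0.18, camera adjusted p = 0.00513, adjusted p = 0.133 with an estimated correlation, fry adjusted p = 0.00575). Without knockout 0 the group was lost (adjusted p = 0.0697). Their called member Clu rose from 276 ± 10.1 to 396.5 ± 23.1 FPKM (log2 0.54, adjusted p = 0.00142) and kept its call without each library. Complement genes were higher as a group (0 of 17 risen, Cd59a fallen, 16 not past, median log2 0.41, camera adjusted p = 0.0204, adjusted p = 0.313 with an estimated correlation), lost without knockout 0 or wild-type 0 (highest 0.120). Interferon response genes had 0 of 17 called (median log2 0.25, camera adjusted p = 0.0214, adjusted p = 0.488 with an estimated correlation), lost without knockout 0 or wild-type 1 (highest 0.582).

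Immediate early genes were lower in knockout retina in 16 of 17 members, with 0 risen, Btg2 fallen and 16 not past the threshold, or 2 fallen over the list alone (median log2 -0.36, camera adjusted p = 1.15e-06, adjusted p = 0.313 with an estimated correlation). Btg2 fell (log2 -0.36, adjusted p = 0.0112), lost without knockout 1 or wild-type 1 (highest 0.0913). Lysosome and phagocytosis genes had 2 of 24 risen, 1 fallen and 21 not past, or 6 and 1 over the list alone (median log2 0.05, camera adjusted p = 0.00513, adjusted p = 0.313 with an estimated correlation). Among them Cd36 fell (log2 -1.17, adjusted p = 0.0112) and kept its call without each library. Itgav rose (log2 0.45, adjusted p = 0.0144), lost without knockout 2 or wild-type 1 or 2 (highest 0.0879), and Gpnmb rose (log2 0.83, adjusted p = 0.0411), lost without knockout 1 or 2 or wild-type 0 or 1 (highest 0.201). Cone phototransduction genes were higher in 11 of 12 members, with Slc24a2 risen, 0 fallen and 11 not past (median log2 0.21, camera adjusted p = 2.95e-04, adjusted p = 0.313 with an estimated correlation). Slc24a2 rose by log2 0.27 (adjusted p = 0.0352), lost without knockout 1 or 2 or any wild-type library (highest 0.163). With the term for lens content Btg2, Cd36, Itgav, Gpnmb, Slc24a2 and Slc6a20a were no longer called, with log2 at 74.6% to 112% and SE at 113% to 133% of those without it.

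Further lists moved little in knockout retina. Photoreceptor structure and identity genes were slightly lower (0 of 23 risen, Fscn2 fallen, 22 not past, median log2 -0.09, camera adjusted p = 0.0372, adjusted p = 0.448 with an estimated correlation), lost without knockout 0 or 1 or wild-type 0 (highest 0.159). Fscn2 (log2 -0.28, adjusted p = 0.0466, overlapping groups) lost its call without any 1 library (highest 0.176). Cholesterol synthesis genes (0 of 21 called, median log2 -0.10, camera adjusted p = 0.0169, adjusted p = 0.488 with an estimated correlation) were lost without knockout 2 or wild-type 1 (highest 0.155). Cytosolic ribosomal proteins (0 of 72 called, median log2 0.05, camera adjusted p = 0.0186, adjusted p = 0.622 with an estimated correlation) were lost without the same pair of libraries (highest 0.297). Angiogenesis factors did not pass camera (adjusted p = 0.105) but passed fry (adjusted p = 0.00549), with Flt1 risen (log2 0.35, adjusted p = 0.0128, lost without knockout 1 at 0.102). The unfolded protein response did not shift (32 measured, 0 risen, Asns fallen, median log2 -0.02, camera adjusted p = 0.349), and Asns (log2 -0.50, adjusted p = 0.024) lost its call without any wild-type library (highest 0.0900). With the lens term Flt1 (adjusted p = 0.113), Asns (0.255) and Fscn2 (0.229) were no longer called, with log2 at 71.4% to 97.3% and SE at 117% to 131%. Neb, of the skeletal muscle list, fell at under 1 FPKM (log2 -1.41, adjusted p = 0.0319, lost without knockout 1 or wild-type 0 or 1, highest 0.150). Rod phototransduction (adjusted p = 0.258), the proteasome (0.336), apoptosis (0.336), the circadian clock (0.336) and heat shock chaperones (0.336) did not pass.

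**Figure D2:**
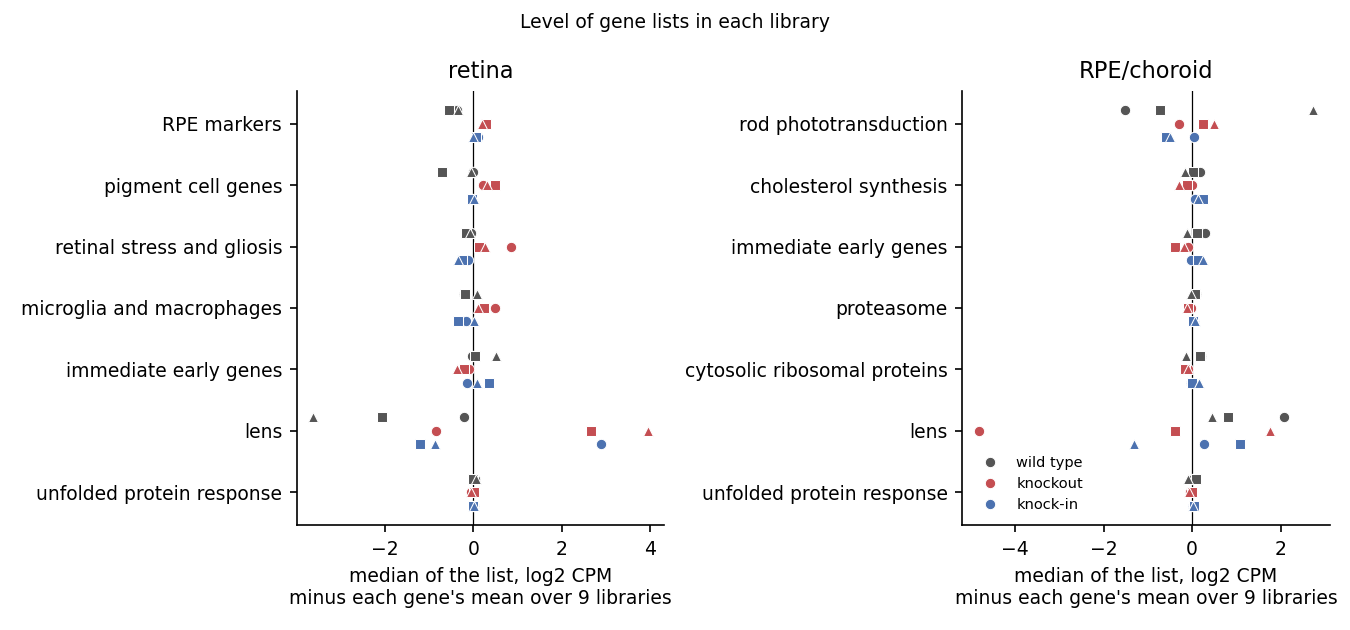
Median log2 level per library (horizontal axis, relative to each gene's mean over the 9 libraries of a tissue) of 7 gene lists in retina and 7 in RPE/choroid (vertical axis). Each library has 1 marker, with 3 libraries per genotype. RPE markers in retina stand at 0.20 to 0.29 in knockout and -0.54 to -0.34 in wild type.

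Fewer genes differed between knock-in and wild-type retina, 39 of 14699, with 21 higher and 18 lower in knock-in. The comparison asks what the altered protein does with Abca4 transcripts at 80.4% of wild type. Single genes such as Alpk1, Hdc, Stau2 and Gpsm3 changed, and the unfolded protein response, the response to misfolded proteins, did not shift as a group. RPE markers were higher here too. Of the 39 genes, 17 changed at least 2-fold, and 1250 genes had an unadjusted p under 0.05 where 735 are expected. The count was 23 without knock-in library 1 and 15 without wild-type library 1. The authors' deposited comparison calls 290 genes (226 upward, 64 downward), of which 34 were also called here, with the same direction.

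Alpk1, an innate immune kinase gene near Abca4 on chromosome 3, fell from 2.54 ± 0.247 to 0.597 ± 0.055 FPKM in knock-in retina (log2 -2.07, SE 0.126, adjusted p = 2.08e-06). Hdc fell from 2.51 ± 0.245 to 0.526 ± 0.0278 FPKM (log2 -2.23, adjusted p = 4.25e-04) and Ccdc115 (log2 -0.68, adjusted p = 4.25e-04). Stau2, which binds double-stranded RNA, rose from 19.6 ± 3.26 to 29.5 ± 5.43 FPKM (log2 0.56, adjusted p = 4.25e-04), Gpsm3 from 11.3 ± 2.54 to 23.9 ± 4.38 FPKM (log2 1.13, adjusted p = 0.0015) and Ift57 by log2 1.18 (adjusted p = 0.00192). Ssbp4 (log2 1.285, adjusted p = 0.00192), Rab37 (log2 1.47, adjusted p = 0.00462), Sema7a (log2 0.71, adjusted p = 0.00192) and Arhgap29 (log2 0.95, adjusted p = 0.00462) rose as well. These 10 genes kept their calls without each single library. All knock-in retinal libraries were female, and with a term for sex Rab37 (adjusted p = 0.0783), Ssbp4 (0.0814) and Arhgap29 (0.0593) were no longer called, as SE grew to 130% to 141% while log2 stayed at 96.9% to 101% of those without it.

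The remaining large knock-in changes in retina lost their calls in some fits with 1 library fewer, where log2 lay between 83.8% and 121% of the reported value. Tcea3 (log2 1.92) lost its call without knock-in 2 or wild-type 0 or 1 (highest 0.163). Isyna1 (log2 1.10) was lost without wild-type 1 (0.0524). Tnip1 (log2 0.495) was lost without any knock-in library or wild-type 0 or 1 (highest 0.237). Lyrm7 (log2 -1.58) was lost without knock-in 0 or 2 or wild-type 0 or 1 (highest 0.113). Snhg6 (log2 -0.825) lost its call without wild-type 1 (0.0508), and Tifa (log2 -0.66), whose protein acts downstream of Alpk1, without knock-in 0 or 1 or wild-type 1 or 2 (highest 0.0736). Cacna2d3 (log2 -0.57) lost its call without any knock-in library or wild-type 1 or 2 (highest 0.194). Col19a1 (log2 -0.555) was lost without knock-in 0 or 1 or any wild-type library (highest 0.158). Cd200 (log2 -0.52) was lost without knock-in 0 or 1 or any wild-type library (highest 0.124). Hist2h2be (log2 -0.47) was lost without any 1 library (highest 0.206). None of these 10 genes was called with the term for sex, where the largest p belonged to Cacna2d3 (adjusted p = 0.166), log2 was 81.9% to 103% and SE 117% to 129% of those without it. The lens term ended the calls of Cacna2d3, Col19a1, Cd200 and Hist2h2be, with log2 at 75% to 94.9% and SE at 81% to 113%.

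Of the gene lists, RPE markers were higher in knock-in retina, with 0 of 21 called over all genes, and 6 risen and 0 fallen adjusted over the list alone (median log2 0.53, camera adjusted p = 2.26e-10, adjusted p = 0.0312 with an estimated correlation). This group passed without each library, although Rpe65 alone did not (log2 0.84, adjusted p = 0.121). Lens genes (0 of 18 called, median log2 2.79, camera adjusted p = 9.96e-07) and choroid matrix genes (0 of 22 called, median log2 0.41, camera adjusted p = 7.02e-09) were higher, with lens signal concentrated in knock-in library 0, and both had adjusted p = 0.639 with an estimated correlation. Cytosolic ribosomal proteins were slightly lower (0 of 72 called, median log2 -0.06, camera adjusted p = 2.76e-04, adjusted p = 0.639 with an estimated correlation). The unfolded protein response (32 measured, 0 called, median log2 0.02, adjusted p = 0.927) and retinal stress and gliosis (15 measured, 0 called, median log2 -0.03, adjusted p = 0.0654) did not pass.

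Other list shifts in knock-in retina were lost in some fits with 1 library fewer, with 0 members called over all genes. Rod phototransduction (20 measured, median log2 -0.08, camera adjusted p = 0.00582) was lost without wild-type 0 (0.0584). The proteasome (31 measured, median log2 -0.04, adjusted p = 0.0214) was lost without knock-in 0 or wild-type 1 (highest 0.152). Interferon response genes (17 measured, median log2 -0.20, adjusted p = 0.0196) were lost without knock-in 1 or 2 or wild-type 0 or 2 (highest 0.115). Cholesterol synthesis (21 measured, median log2 -0.11, adjusted p = 0.00582) was lost without knock-in 0 or wild-type 1 (highest 0.0780). Pigment cell genes (13 measured, 1 risen over the list alone, median log2 0.26, adjusted p = 0.00361) were lost without wild-type 1 (0.336). Fibroblast and sclera genes (11 measured, median log2 0.65, adjusted p = 0.0181) were lost without knock-in 0 or 2 or wild-type 0 (highest 0.362). The nuclear-encoded respiratory chain (30 measured, median log2 -0.06, adjusted p = 0.00761) was lost without knock-in 0 or wild-type 2 (highest 0.362). The respiratory chain had adjusted p = 0.667 with an estimated correlation and the other 6 lists adjusted p = 0.639 with an estimated correlation.

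**Figure D3:**
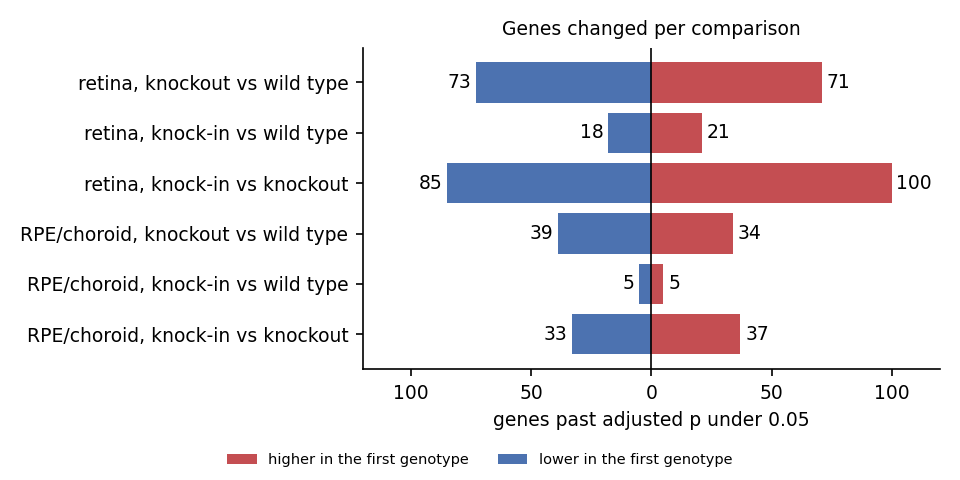
Number of genes (horizontal axis) called higher or lower in the genotype named first at an adjusted p under 0.05 per comparison in retina and RPE/choroid, 3 libraries per group. Knock-in against wild type gives 39 genes in retina and 10 in RPE/choroid, the fewest in each tissue.

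Knock-in and knockout retina differed directly in 185 of 14699 genes, 100 higher and 85 lower in knock-in. The comparison asks which knockout changes are absent when an altered protein is made. Ppara, Fgf2, Tc2n and Pttg1 were lower in knock-in, Wdr63, Kif27 and Foxj1 were higher, and stress, microglial and interferon genes were lower by camera but not with an estimated correlation (adjusted p = 0.108, 0.201 and 0.201). There were 46 genes with at least a 2-fold difference and 1716 with an unadjusted p under 0.05 where 735 are expected. The count was 110 without knock-in library 1 and 103 without knockout library 1. The authors' deposited comparison calls 323 genes (117 upward, 206 downward), of which 116 were also called here, with the same direction.

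Ppara was lower in knock-in than in knockout retina (log2 -4.05, adjusted p = 1.51e-09), and Pttg1 (log2 -4.46, adjusted p = 0.00488), Tc2n (log2 -3.53), Fgf2 (log2 -2.09, adjusted p = 4.55e-04) and its neighbour Nudt6 (log2 -1.27) were lower as well. Alpk1 (log2 -1.99, adjusted p = 1.04e-06), the centrin gene Cetn4 (log2 -1.40, adjusted p = 2.06e-04), Spata6 (log2 -1.16) and the nicotinic receptor gene Chrna5 (log2 -1.11) were also lower. Higher in knock-in were Wdr63 (log2 1.655, adjusted p = 7.92e-04), Kif27 (log2 1.41, adjusted p = 1.84e-04), Pla2g4b (log2 1.30), Foxj1 (log2 1.17, adjusted p = 0.00357), Ttc21a (log2 1.13), Rab37 (log2 1.47) and Ssbp4 (log2 1.18). These 16 genes kept their calls without each single library. The X-linked gene Lancl3 (log2 1.15, adjusted p = 0.00957) lost its call without knockout 1 (0.0699). Tcea3 (log2 1.48) was lost without knock-in 2 or any knockout library (highest 0.0954). Jmjd7 (log2 1.31) was lost without knock-in 0 or 1 or knockout 0 or 1 (highest 0.109). Lyrm7 (log2 -1.31) was lost without knock-in 0 or 2 or knockout 2 (highest 0.0925) and with the lens term (0.0520, log2 -1.22).

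Retinal stress and gliosis genes were lower in knock-in than in knockout in all 15 members, with 0 risen, Fgf2 fallen and 14 not past the threshold, or 7 fallen adjusted over the list alone (median log2 -0.60, camera adjusted p = 2.11e-14, adjusted p = 0.108 with an estimated correlation, fry adjusted p = 0.0272). Interferon response genes (17 measured, 0 called, 5 fallen over the list alone, median log2 -0.41, camera adjusted p = 1.11e-06), microglia and macrophage genes (18 measured, Ctss fallen, 17 not past, median log2 -0.44, camera adjusted p = 3.10e-06) and complement genes (17 measured, 0 called, 1 risen and 5 fallen over the list alone, median log2 -0.31, camera adjusted p = 6.08e-04) were lower too, each with adjusted p = 0.201 with an estimated correlation. Ctss, a microglial protease, stood at 10.2 ± 0.947 FPKM in knock-in and 18.4 ± 3.79 in knockout (log2 -0.86, adjusted p = 0.0118), lost without knock-in 0 or 1 (highest 0.0680). Immediate early genes were higher in knock-in (1 of 17 risen, 0 fallen, 16 not past, median log2 0.46, camera adjusted p = 1.00e-06, adjusted p = 0.243 with an estimated correlation), with Btg2 risen (log2 0.46, adjusted p = 0.00158).

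RPE markers (21 measured, 0 called, median log2 -0.26, camera adjusted p = 3.95e-04), cone genes (12 measured, Slc24a2 fallen, 11 not past, median log2 -0.20, adjusted p = 2.50e-04), lysosome and phagocytosis genes (24 measured, 1 risen, 2 fallen, 21 not past, median log2 -0.09, adjusted p = 2.61e-04), the proteasome (31 measured, 0 called, median log2 -0.08, adjusted p = 0.00103, fry adjusted p = 0.0214) and oxidative stress genes (22 measured, Mt1 fallen, 21 not past, median log2 -0.05, adjusted p = 0.00947) were lower in knock-in than in knockout retina, each with adjusted p = 0.201 with an estimated correlation. Cytosolic ribosomal proteins (72 measured, 0 called, median log2 -0.11, camera adjusted p = 2.81e-09) and pigment cell genes (13 measured, 1 risen, 1 fallen, 11 not past, median log2 -0.32, adjusted p = 0.00417) were lower with adjusted p = 0.307 with an estimated correlation. Müller glia genes (15 measured, Clu fallen with log2 -0.45 and adjusted p = 0.00391, 14 not past, median log2 -0.14, adjusted p = 0.00947, and 0.201 with an estimated correlation) were lost without knockout 0 (0.0811). The respiratory chain (30 measured, 0 called, median log2 -0.07, adjusted p = 0.0066, and 0.658 with an estimated correlation) was lost without knock-in 0 (0.302). Retinoid cycle genes (17 measured, 0 called, median log2 -0.18, adjusted p = 0.0247, and 0.599 with an estimated correlation) were lost without knock-in 0 or 2 or knockout 0 (highest 0.557). Lens genes (18 measured, 0 called, median log2 -1.34, adjusted p = 0.011, and 0.758 with an estimated correlation) were lost without knock-in 1 or 2 or knockout 1 or 2 (highest 0.411).

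Several list members were called between knock-in and knockout retina and lost the call in some fits with 1 library fewer. Sag, the rod arrestin gene, was lower in knock-in (4225 ± 235 against 5222 ± 280 FPKM, log2 -0.30, adjusted p = 0.0473), lost without knock-in 0 or 1 or knockout 1 or 2 (highest 0.164). Slc24a2 (log2 -0.26) was lost without knock-in 1 or 2 or any knockout library (highest 0.141), Rpgrip1 (log2 0.43) without knock-in 0 or 1 or any knockout library (highest 0.150), and Asns (log2 0.46) without any knock-in library (highest 0.104). Abca1 (log2 -0.40) was lost without knock-in 1 or 2 or knockout 0 or 2 (highest 0.122), Abca13 (log2 -0.45) without any 1 library (highest 0.120), and Mt1 (log2 -0.43) without knock-in 0 or 1 or knockout 0 or 2 (highest 0.106). Mertk (log2 -0.69) was lost without knock-in 0 or 2 or knockout 1 or 2 (highest 0.109). Cd36 (log2 0.96) was lost without knock-in 1 or 2 or knockout 1 or 2 (highest 0.0942). Gpnmb (log2 -0.77) was lost without any knock-in library or knockout 1 or 2 (highest 0.203). Mc1r (log2 0.70) was lost without knock-in 1 or 2 or any knockout library (highest 0.161) and Flt1 (log2 -0.31) without any knock-in library or knockout 1 (highest 0.134). The lens term ended the calls of Sag, Gpnmb and Mc1r, and the sex term that of Mc1r, with log2 at 85.2% to 98.8% and SE at 99.7% to 115% of those without them.

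RPE/choroid of knockout mice had 73 of 15454 genes changed, 34 higher and 39 lower. The comparison asks what the tissue that takes up photoreceptor outer segments does when they lack Abca4. Pttg1, Slfn8, Snx31 and Lgals7 rose, Npy, Car4, Xaf1 and Il12b fell, and ribosomal, proteasomal and immediate early genes were lower by camera but not with an estimated correlation (each adjusted p = 0.727). Of the 73 genes, 32 changed at least 2-fold, and 2401 genes had an unadjusted p under 0.05 where 773 are expected. The count was 24 without knockout library 1, 25 without knockout 2, 42 without wild-type 0, 22 without wild-type 1 and 462 without wild-type 2. The authors' deposited comparison calls 430 genes (156 upward, 273 downward), of which 51 were also called here, with the same direction.

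Pttg1 rose in knockout RPE/choroid from 5.65 ± 0.942 to 58.1 ± 6.82 FPKM (log2 3.34, SE 0.151, adjusted p = 1.89e-05), Snx31 from 2.35 FPKM to 16.7 ± 3.82 FPKM (log2 2.82, adjusted p = 0.00132), and the galectin gene Lgals7 from 3.35 ± 1.47 to 24.0 ± 3.61 FPKM (log2 2.81, adjusted p = 0.00545). Slfn8, which has close relatives in the genome, rose by log2 3.11 (adjusted p = 2.34e-04). Npy, which encodes neuropeptide Y, fell from 23.7 ± 1.5 to 7.37 ± 0.488 FPKM (log2 -1.74, adjusted p = 4.88e-04), the carbonic anhydrase gene Car4 from 3.00 ± 0.297 to 0.439 ± 0.139 FPKM (log2 -2.81, adjusted p = 0.00139), Xaf1 from 15.6 ± 2.64 to 4.40 ± 0.287 FPKM (log2 -1.83, adjusted p = 0.003). Il12b, a subunit of interleukin 12, also fell (log2 -2.09, adjusted p = 0.00336). BC002163, a near copy of Ndufs5, fell from 93.0 ± 20.8 to 0.347 ± 0.321 FPKM (log2 -7.97, adjusted p = 2.18e-05), and the unnamed transcript AA465934 from 40.2 to 3.16 FPKM (log2 -3.72, adjusted p = 6.15e-05). These 10 genes kept their calls without each single library.

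Other knockout changes in RPE/choroid lost their calls in some fits with 1 library fewer, where log2 lay between 78.2% and 116% of the reported value. C4b, of the complement cascade, rose from 18.6 ± 0.917 to 33.1 ± 5.45 FPKM (log2 0.80, adjusted p = 0.0443), lost without knockout 0 or wild-type 0 or 1 (highest 0.131). Rab3b (log2 2.51, adjusted p = 0.0184) was lost without knockout 1 or 2 or wild-type 1 (highest 0.0852). Rhbdl2 (log2 1.78), Mrps12 (log2 0.99) and Ppp1r1b (log2 0.83) were lost without any knockout library or wild-type 0 or 1 (highest 0.148, 0.123 and 0.162), as were the falls of Hist1h4j (log2 -2.96, highest 0.166), a histone gene with near copies, and Ooep (log2 -1.35, highest 0.211). Tnfaip6 (log2 -1.38) was lost without knockout 1 or 2 or wild-type 1 (highest 0.110). The immediate early gene Fosb (log2 -1.88) was lost without knockout 1 or 2 or wild-type 0 or 1 (highest 0.119). With a term for sex, Ppp1r1b (adjusted p = 0.0584), C4b (0.0678) and Ooep (0.0632) were no longer called, with SE at 105% to 107% and the same log2. These groups were male, and the term stands in this tissue for knock-in library 2, the only female one.

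**Figure D4:**
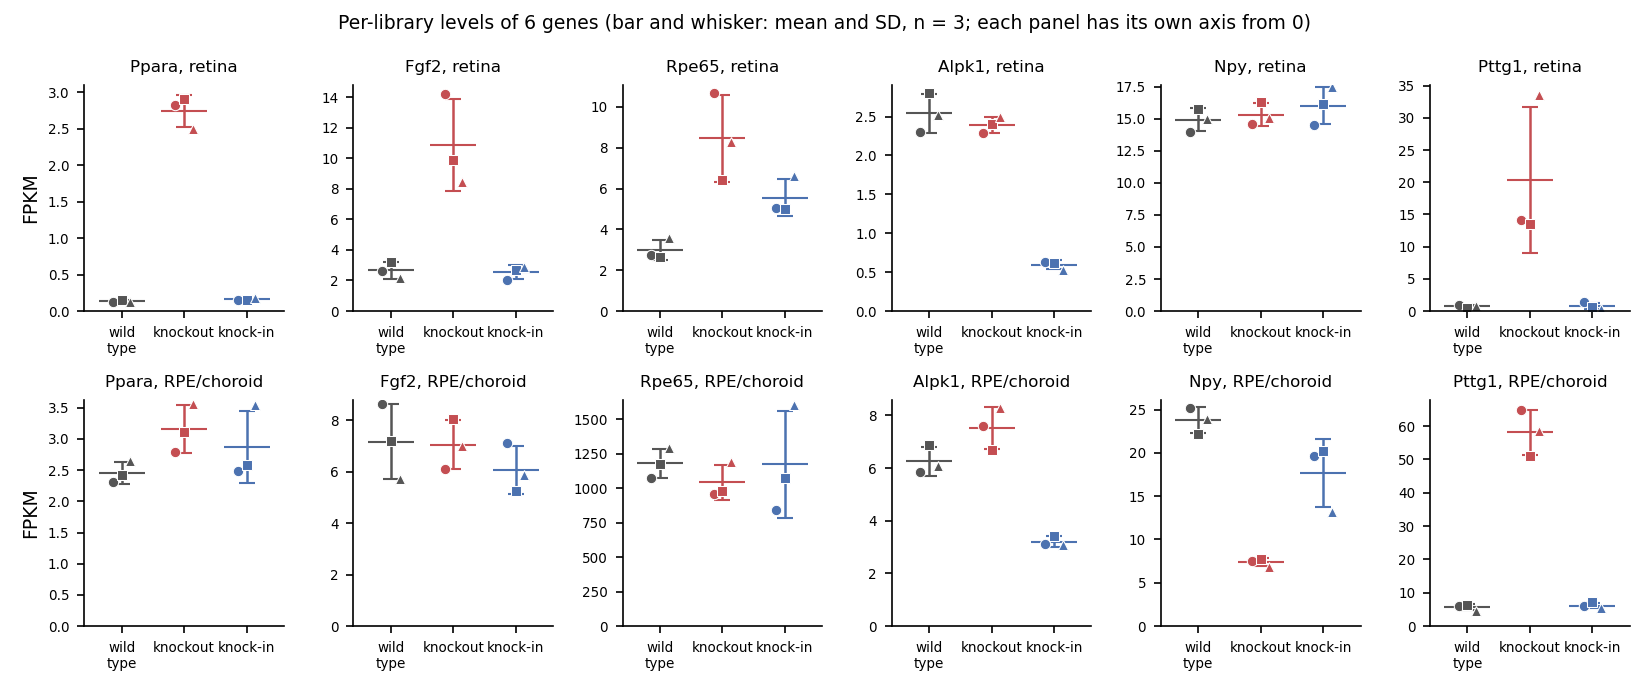
FPKM (vertical axis) of Ppara, Fgf2, Rpe65, Alpk1, Npy and Pttg1 per library (points) with mean and SD (bars and whiskers), 3 libraries per genotype, in retina and RPE/choroid. Ppara rises in knockout retina to 2.74 FPKM, and Npy falls in knockout RPE/choroid to 7.37 FPKM.

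Cytosolic ribosomal proteins were lower in knockout RPE/choroid in 71 of 72 members with 0 called (median log2 -0.21, camera adjusted p = 3.66e-15). Lower as well were immediate early genes (15 measured, 0 risen, Fosb fallen, 14 not past, 3 fallen over the list alone, median log2 -0.32, adjusted p = 7.57e-05), the respiratory chain (30 measured, 0 called, 3 fallen over the list alone, median log2 -0.11, adjusted p = 1.96e-04) and the proteasome (31 measured, 0 called, 5 fallen over the list alone, median log2 -0.09, adjusted p = 6.21e-04). Endothelial genes were higher (15 measured, 0 called, median log2 0.13, adjusted p = 0.00539). These 5 lists passed without each library, and each had adjusted p = 0.727 with an estimated correlation.

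Further list shifts in knockout RPE/choroid were lost without single libraries. Microglia and macrophage genes (19 measured, 0 called, median log2 -0.17, camera adjusted p = 0.00324, and adjusted p = 0.727 with an estimated correlation) were lost without wild-type 0 (0.0802). Cholesterol synthesis genes (21 measured, 0 called, median log2 -0.19, adjusted p = 0.00324, and 0.791 with an estimated correlation) were lost without knockout 2 or wild-type 0 (highest 0.127). RPE markers (21 measured, 0 called, median log2 -0.14, adjusted p = 0.0158, and 0.791 with an estimated correlation) and pigment cell genes (15 measured, 0 called, median log2 -0.14, adjusted p = 0.0158, and 0.823 with an estimated correlation) were lost without knockout 2 or wild-type 1 (highest 0.181). Stress and gliosis genes (17 measured, 0 called, median log2 0.15, adjusted p = 0.0472, and 0.727 with an estimated correlation) were lost without knockout 2 or wild-type 2 (highest 0.223). Angiogenesis factors (16 measured, 0 called, 3 risen over the list alone, median log2 0.07, adjusted p = 0.0179, and 0.727 with an estimated correlation) were lost without wild-type 2 (0.0594). Lens genes (18 measured, 0 called, median log2 -0.74, adjusted p = 0.00346, and 0.871 with an estimated correlation) were lost without knockout 0 or wild-type 0 (highest 0.515). Complement genes did not shift as a group (19 measured, C4b risen, 18 not past, adjusted p = 0.904), nor did the unfolded protein response (32 measured, 0 called, median log2 -0.06, adjusted p = 0.128) or the retinoid cycle (17 measured, 0 called, adjusted p = 0.0506).

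Knock-in RPE/choroid differed least from wild type, with 10 of 15454 genes changed, 5 higher and 5 lower. Of the 10, 5 had a called neighbour within 5 Mb, so linked strain variants may contribute. Trim12a and Trim30d rose and Alpk1 fell, while the response to unfolded proteins did not shift. Of the 10 genes, 6 changed at least 2-fold, and 854 genes had an unadjusted p under 0.05 where 773 are expected. The count was 3 without knock-in library 0, 5 without knock-in 1, 2 without knock-in 2 and 2 without wild-type 1. The authors' deposited comparison calls 354 genes (63 upward, 289 downward), of which 7 were also called here, with the same direction.

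Trim12a rose from 0.0677 ± 0.0572 to 5.80 ± 1.13 FPKM in knock-in RPE/choroid (log2 6.49, adjusted p = 4.76e-04) and its neighbour Trim30d by log2 3.999 (adjusted p = 0.00215). Both belong to a cluster of near-identical genes and kept their calls without each library. Alpk1 fell from 6.26 ± 0.539 to 3.21 ± 0.195 FPKM (log2 -0.97, adjusted p = 0.00855), lost without knock-in 0 or 2 or wild-type 1 (highest 0.0676). Arl6ip1 rose from 217 ± 48.4 to 430 ± 147 FPKM (log2 0.98, adjusted p = 0.00855), lost without knock-in 1 or 2 or wild-type 1 (highest 0.0578). The liver-type glycogen phosphorylase gene Pygl rose by log2 0.50 (adjusted p = 0.0263), lost without any knock-in library or wild-type 0 or 1 (highest 0.182). Hbb-b2, which is nearly identical to Hbb-b1, fell (log2 -4.14, adjusted p = 0.0355), lost without any 1 library (highest 0.204) and with the rod term (0.0515, log2 -4.165). Hbb-b1, chosen after its values were seen, moved the other way, at 156, 66.3 and 88.7 FPKM in knock-in and 0.00205, 0 and 5.90 FPKM in wild type, so the fall of Hbb-b2 does not show less globin transcript overall. With a term for sex, Alpk1 (adjusted p = 0.0591), Arl6ip1 (0.0557), Pygl (0.0955) and Hbb-b2 (0.197) were no longer called, with log2 at 92.5% to 104% and SE at 102% to 126% of those without it.

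List shifts in knock-in RPE/choroid mostly involved genes of neighbouring tissue. Rod (20 measured, 0 called, median log2 -1.71, camera adjusted p = 0.00111), cone (11 measured, 0 called, median log2 -1.71, adjusted p = 0.00247) and photoreceptor structure genes (23 measured, 0 called, median log2 -1.62, adjusted p = 0.00137) were lower, each with adjusted p = 0.904 with an estimated correlation. Without wild-type library 2, which carried the most rod transcripts, all 3 lists were instead higher in knock-in (adjusted p = 9.70e-08, 0.0331 and 9.73e-08) with 0 members called and adjusted p = 0.687, 0.724 and 0.687 with an estimated correlation, and photoreceptor structure was also lost without knock-in 2 (0.0910). Skeletal muscle genes were higher (18 measured, 0 called, median log2 0.32, adjusted p = 6.69e-09, and 0.853 with an estimated correlation), without a loss in any left-out library. Ganglion cell genes (12 measured, 0 called, median log2 -0.55, adjusted p = 1.85e-04, and 0.853 with an estimated correlation) were lost without wild-type 2 (0.372). Lens genes (18 measured, 0 called, median log2 -1.01, adjusted p = 0.00137, and 0.904 with an estimated correlation) were lost without knock-in 2 or wild-type 0 (highest 0.271).

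Myelin genes in knock-in RPE/choroid (9 measured, 0 called, median log2 0.16, camera adjusted p = 0.00137, and adjusted p = 0.853 with an estimated correlation) were lost without knock-in 1 or wild-type 2 (highest 0.117). Cholesterol synthesis genes (21 measured, 0 called, median log2 0.13, adjusted p = 0.00168, and 0.904 with an estimated correlation) were lost without the same pair (highest 0.512). Fibroblast and sclera genes (17 measured, 0 called, median log2 -0.09, adjusted p = 0.00179, and 0.894 with an estimated correlation) were lost without knock-in 2 or wild-type 0 (highest 0.432). Ribosomal proteins (72 measured, 0 called, median log2 -0.05, adjusted p = 0.0217, and 0.964 with an estimated correlation) were lost without knock-in 0 or 1 or wild-type 0 or 1 (highest 0.971). Choroid matrix genes (22 measured, 0 called, median log2 -0.06, adjusted p = 0.0217, and 0.853 with an estimated correlation) were lost without knock-in 1 or 2 or wild-type 0 or 2 (highest 0.159). Oxidative stress genes (22 measured, 0 called, median log2 -0.05, adjusted p = 0.0404, and 0.904 with an estimated correlation) were lost without knock-in 0 or 1 or wild-type 1 (highest 0.787). The unfolded protein response (32 measured, 0 called, adjusted p = 0.987), retinal stress and gliosis (17 measured, 0 called, adjusted p = 0.987) and RPE markers (21 measured, 0 called, adjusted p = 0.694) did not shift. Blood genes did not pass (10 measured, Hbb-b2 fallen, adjusted p = 0.0522).

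Between knock-in and knockout RPE/choroid, 70 of 15454 genes differed, 37 higher and 33 lower in knock-in. Chromosome 11 held 18 of the 70 (5.72 expected, Fisher's exact adjusted p = 0.00104). Parental strain variants on this chromosome, which does not carry Abca4, may therefore contribute. Pttg1, Slfn8, Snx31 and Lgals7 were lower in knock-in, Car4, Xaf1 and Il12b higher, and none was called between knock-in and wild type. There were 27 genes with at least a 2-fold difference and 1890 with unadjusted p under 0.05 (773 expected). The count was 29 without knock-in library 0, 33 without knock-in 1, 34 without knock-in 2, 30 without knockout 1 and 28 without knockout 2. The authors' deposited comparison calls 347 genes (145 upward, 201 downward), of which 52 were also called here, with the same direction.

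Pttg1 was lower in knock-in than in knockout RPE/choroid (log2 -3.26, adjusted p = 1.92e-05), as were Slfn8 (log2 -3.295, adjusted p = 1.43e-04), Snx31 (log2 -2.70, adjusted p = 0.00124) and Alpk1 (log2 -1.23, adjusted p = 4.88e-04). Higher were Trim12a (5.80 against 0.00792 FPKM, adjusted p = 7.08e-05), Trim30d (log2 4.34), BC002163 (log2 8.08, adjusted p = 1.92e-05), AA465934 (log2 3.46), Car4 (log2 2.585, adjusted p = 0.00218), Xaf1 (log2 1.83, adjusted p = 0.00306) and Fam69c (1.79 to 5.81 FPKM, log2 1.705, adjusted p = 0.00542). These 11 genes kept their calls without each single library. Lgals7 (log2 -2.69) lost its call without knock-in 0 (0.0559), Mrps12 (log2 -1.27) without knock-in 1 (0.0541), Myl4 (log2 1.26) without knock-in 0 or 2 (highest 0.0541), and Il12b (log2 1.75) without knock-in 0 or knockout 1 or 2 (highest 0.0773). Rab3b (log2 -2.45) lost its call without any knock-in library or knockout 1 or 2 (highest 0.111), Ppp1r1b (log2 -0.996) without any knock-in library or knockout 2 (highest 0.0852), and C4b (log2 -0.82) without any knock-in library or knockout 0 (highest 0.165). Slc6a4 (log2 1.47, highest 0.196), Rhbdl2 (log2 -1.585, highest 0.196) and Hbb-b2 (log2 -3.085, highest 0.172) lost their calls without any 1 library. With the sex term Rab3b, Rhbdl2, Ppp1r1b, C4b, Slc6a4 and Hbb-b2 were no longer called (adjusted p = 0.0692 to 0.170), with log2 at 93.2% to 102% and SE at 112% to 124% of those without it.

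Ribosomal proteins (72 measured, 0 called, median log2 0.16, camera adjusted p = 5.67e-10), cholesterol synthesis (21 measured, 0 called, 4 risen over the list alone, median log2 0.29, adjusted p = 2.61e-09), immediate early genes (15 measured, 0 called, 1 risen over the list alone, median log2 0.30, adjusted p = 6.74e-06), the proteasome (31 measured, 0 called, median log2 0.11, adjusted p = 8.41e-05) and the respiratory chain (30 measured, 0 called, median log2 0.10, adjusted p = 2.59e-04) were higher in knock-in than in knockout RPE/choroid. These 5 lists passed without each library, and each had adjusted p = 0.760 with an estimated correlation. Antigen presentation genes (13 measured, 0 called, median log2 0.24, adjusted p = 0.0133) were lost without knock-in 1 or knockout 2 (highest 0.343). Microglia and macrophage genes (19 measured, 0 called, median log2 0.10, adjusted p = 0.047) were lost without the same pair (highest 0.304). RPE markers (21 measured, 0 called, median log2 0.14, adjusted p = 0.040) were lost without knock-in 2 or knockout 2 (highest 0.605). Stress and gliosis genes (17 measured, 0 called, 2 fallen over the list alone, median log2 -0.15, adjusted p = 0.0447) were lost without the same libraries (highest 0.127). Skeletal muscle genes (18 measured, 0 called, median log2 0.21, adjusted p = 0.00391) were lost without knock-in 0 or knockout 1 (highest 0.854). Endothelial genes (15 measured, 0 called, median log2 -0.09, adjusted p = 0.047) were lost without knock-in 1 or 2 or knockout 0 or 2 (highest 0.377). Angiogenesis factors (16 measured, 0 called, 2 fallen over the list alone, median log2 -0.03, adjusted p = 0.047) were lost without knock-in 1 or 2 or knockout 0 (highest 0.205). Transporters of the ABCA class without Abca4 (10 measured, 0 called, 2 fallen over the list alone, median log2 -0.07, adjusted p = 0.047) were lost without knock-in 0 or 1 or knockout 0 or 2 (highest 0.0916). Bipolar cell genes (12 measured, 0 called, median log2 -0.62, adjusted p = 0.047, and 0.763 with an estimated correlation) were lost without knock-in 1 or 2 or knockout 1 or 2 (highest 0.180). Apart from bipolar cell genes, these lists also had adjusted p = 0.760 with an estimated correlation.

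A call in 1 tissue alone does not show a difference between tissues, which was tested as an interaction over 16222 genes. The knockout effect differed between RPE/choroid and retina for 22 genes (6 more positive and 16 more negative in RPE/choroid, 1988 at an unadjusted p under 0.05 where 811 are expected), the knock-in effect for 9 genes (6 and 3) and the contrast of knock-in and knockout for 27 genes (16 and 11). Ppara differed most, rising in knockout retina by log2 4.32 and at log2 0.35 in knockout RPE/choroid (adjusted p = 0.115, difference adjusted p = 6.97e-10). Fgf2 rose in knockout retina and not in RPE/choroid (log2 -0.03, difference adjusted p = 0.0208), and Npy fell in knockout RPE/choroid and not in retina (log2 0.05, difference adjusted p = 3.02e-04). Rpe65, Rgr and Oca2 were higher in knockout retina while their RPE/choroid values were log2 -0.14, -0.24 and -0.08 (difference adjusted p = 0.00565, 0.00976 and 0.0158). In knock-in, Alpk1 fell more in retina than in RPE/choroid (difference adjusted p = 0.010), and Ssbp4 rose in retina and not in RPE/choroid (log2 -0.04, difference adjusted p = 0.010). The count for knockout was 60 without retinal knockout 0, 9 without retinal wild-type 0, 11 without wild-type 1 of either tissue and 337 without RPE/choroid wild-type 2. For knock-in it was 2 without retinal knock-in 2 and 4 or 5 without others, except retinal knock-in 1 (7) and RPE/choroid wild-type 0 (10) or 2 (6). The 27 genes became 14 to 17 without retinal knock-in 0 or 1, retinal knockout 1 or RPE/choroid knock-in 1, 12 without RPE/choroid knock-in 2, and 42, 7 and 11 without RPE/choroid knockout 0, 1 and 2.

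Knockout and knock-in retina shared 11 called genes with the same direction, where simulations of unchanged groups with the same shared controls gave 0.15 on average. Arhgap29, Ift57, Sntg1 and Stau2 were higher in both and Cacna2d3, Ccdc115, Hdc, Hunk, Snhg6, Dnahc7b and a gene without a standard name were lower. They were listed after their values were seen. Across all retinal genes the covariance of both effects was 0.104, against 0.0395 (SD 0.0063) in the simulations. Whether lens content, which differs between libraries, adds to this covariance was not tested. In RPE/choroid 3 genes were shared, among them Ptprz1, where simulations gave 0.03, with a covariance of 0.0626 against 0.0404 (SD 0.0036). The correlation exceeded the simulations in retina (r = 0.65 against 0.534) but not in RPE/choroid (0.471 against 0.492). Shares of genes with the same sign were close (67.2% against 67.6%, and 66.9% against 66.5%).

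Genes within 10 Mb of Abca4 changed more often than others in retina, an excess that did not pass the threshold within 20 Mb in knockout (odds ratio 1.51, Fisher's exact p = 0.457) or within 5 Mb in knock-in (exact p = 0.0816). Within 10 Mb of Abca4, 3 of 82 tested genes changed in knockout retina (Arhgap29, Bcar3 and Cnn3, odds ratio 3.93, Fisher's exact p = 0.0458), 4 of 82 in knock-in retina (Alpk1, Arhgap29, Tifa and a gene without a standard name, odds ratio 21.3, exact p = 6.38e-05) and 7 of 82 between knock-in and knockout (odds ratio 7.61, exact p = 7.41e-05). The genes of this window were counted as a set and named after their values were seen. In RPE/choroid 0 of 86 were called by edgeR in knockout (exact p = 1.0), and Alpk1 alone in knock-in (odds ratio 20.1, exact p = 0.0543) and between knock-in and knockout (exact p = 0.324).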

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

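The tests of explanations in this part were chosen after the results were seen, and the counts over other splits of the libraries before. Without a sex term, the effect of genotype differed between tissues for 22 genes in knockout, 9 in knock-in and 27 between knock-in and knockout. Given as log2 in RPE/choroid minus log2 in retina, the knockout effects differed by -3.96 for Ppara, -1.775 for Npy, -1.61 for Rpe65, -1.67 for Rgr, -1.62 for Oca2, -2.08 for Fgf2, -1.59 for Nudt6, -2.85 for Car4 and -2.80 for AA465934. Knock-in effects differed by 4.23 for Trim30d, 1.09 for Alpk1, 0.89 for Arl6ip1, -1.34 for Ssbp4, -1.32 for Gpsm3 and -1.03 for Isyna1. The contrasts of knock-in and knockout differed by 3.885 for Ppara, 4.56 for Trim30d, 1.19 for Spata6, -1.19 for Ssbp4, 1.87 for Fgf2 and -2.08 for Lancl3. Among 40 splits of the libraries, the real one included, 2 gave as many genes as the 22 in knockout (highest other 29), 3 as many as the 9 in knock-in (highest other 37) and 6 as many as the 27 between knock-in and knockout (highest other 127), so chance is not excluded for these 3 counts, by a margin of 1 split for knockout, and the highest others of the last pair, several times the real counts, point to a structure of these samples.

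RPE genes were higher in knockout retina, and RPE cells carried over with the retina are a candidate explanation. Unlisted genes, in none of the RPE lists, had at least 50 FPKM in RPE/choroid and 20 times the retinal level. Of these, 141 of 179 were higher in knockout retina and 133 in knock-in. Chance lows in the shared wild-type libraries would raise both counts. The median rise in knockout was 0.456% of the RPE/choroid level (quartiles 0.017% and 1.15%), against 0.587% (quartiles 0.47% and 0.82%) for the 13 listed markers. The shares of unlisted genes were not uniform (rho 0.113 of increment and RPE/choroid level), and genes of choroid, muscle, lens and other tissues gave 0.12% over 27 genes, which argues against material of the whole tissue at an equal share. Increments of the listed markers follow their RPE/choroid level (rho 0.94), against what was set for higher expression of single genes within retinal cells, but their wild-type retinal levels already do so (rho 0.802) and any common fold would give a high rho, so both explanations stay open. Ppara stands at 2.74 FPKM in knockout retina, as high as in RPE/choroid itself, and so cannot come from such a share, and the levels of both tissues were scaled separately by the authors' software.

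Called genes lay close together on chromosomes, and parental strain variants may account for part of the calls. In all 4 comparisons with wild type, more called genes had a called neighbour within 5 Mb than in 10000 random sets, with 85 of 143 against 72.6 in knockout retina (permutation p = 0.04), 17 of 38 against 6.93 in knock-in retina (permutation p = 0.0035), 43 of 73 against 23.2 in knockout RPE/choroid (permutation p = 3e-04) and 5 of 10 against 0.486 in knock-in RPE/choroid (permutation p = 6e-04). Reads shared by adjacent genes do not account for it alone. The excess stayed in all 4 with genes within 0.1 Mb counted once (permutation p = 0.046, 0.015, 2e-04 and 0.0014). Chromosome 11 held 16 of 73 called genes of knockout RPE/choroid (5.96 expected, Fisher's exact adjusted p = 0.00803). Chromosome 1 held 9 of 38 in knock-in retina (2.22 expected, same adjusted p). BC002163 stood at 45.6, 0.853 and 0 FPKM in knockout retina, so a variant may differ within 1 genotype. A changed gene that altered its neighbours would give the same counts, so a genotype effect here stays open.

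Abca4 transcripts in RPE/choroid could come from retina carried over with it. From rod genes, the retinal share was 9.99% in wild-type library 2 and 0.446% to 2.07% in the other 8 libraries. Carry-over alone does not account for Abca4 in wild type, as it predicts 3.19% of the level measured in wild-type library 0, but it predicts 112% of the excess in wild-type library 2 (25.3 of 22.6 FPKM). After subtraction the level was 35.0 ± 1.32 FPKM in wild type, 24.9 ± 0.76 (71.1%) in knockout and 36.4 ± 3.61 (104%) in knock-in RPE/choroid, so the spread in wild type is in line with retinal material in 1 library. Separate scaling of the tissues makes these shares approximate.

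For the counts of genes within a tissue the 10 splits of 6 libraries are too few for a share under 0.05. The real split was the 1 split with as many genes in each comparison: 144 in knockout retina (highest other 8), 39 in knock-in retina (0), 185 between knock-in and knockout retina (148), 73 in knockout RPE/choroid (1), 10 in knock-in RPE/choroid (4) and 70 between knock-in and knockout RPE/choroid (0). The split with 148 genes joins knock-in library 0 with knockout libraries 1 and 2, the retinal libraries rich in lens transcripts, so lens content may account for part of the 185 genes. For lists, 1 split, the real one, gave as many as the 16 in knockout retina (highest other 11), the 11 in knock-in retina (9) and the 16 between knock-in and knockout retina (15). In RPE/choroid 9 of the 10 splits gave as many lists as the 12 in knockout (highest other 27), 9 as many as the 12 in knock-in (highest other 22) and 3 as many as the 14 between knock-in and knockout (highest other 23). List shifts in RPE/choroid may therefore reflect a structure of these samples, such as their content of neighbouring tissue.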

How the results depend on the processing

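Added terms and fits without several libraries were chosen after the results were seen, the other alternatives before. Counts of called genes moved with the tool, with its input and with a fold threshold. For knockout against wild type, knock-in against wild type and knock-in against knockout, the counts in retina of 144, 39 and 185 became 323, 115 and 322 with DESeq2, 27, 10 and 18 with limma on log2(FPKM + 1), 26, 11 and 18 with limma on log2(FPKM + 0.1) and 8, 5 and 16 with glmTreat against 1.5-fold. In RPE/choroid the 73, 10 and 70 genes became 522, 43 and 309 with DESeq2, 19, 5 and 26 and then 18, 1 and 23 with the limma settings, and 13, 2 and 13 with glmTreat. RLE scaling moved no count by over 1.5 times. A term for sex moved knock-in against wild type to 14 genes in retina and 2 in RPE/choroid, and knock-in against knockout to 289 and 36. A lens term gave 67 genes in knockout retina, and without knockout libraries 0 and 2 the counts were 63 for knockout and 45 for knock-in against knockout. That fit keeps 1 knockout library, assumed to vary like the other groups, so its counts say little about the libraries left out. In RPE/choroid a rod term gave 370 genes for knockout and 186 for knock-in against knockout, fits of the compared libraries alone gave 33, 5 and 198 genes, and knock-in against knockout gave 190 without wild-type library 2 in the fit. Causes of these shifts were not tested.

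The library numbers pair nothing: libraries of 1 number correlated no better (median r -0.001 in retina, -0.049 in RPE/choroid) than libraries of different numbers (-0.003 and 0.02). With the table number as a block, the RPE/choroid counts were 28, 4 and 36, and Abca4 in knock-in retina was log2 -0.303.

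Abca4 in knock-in retina passed with DESeq2 (log2 -0.299, adjusted p = 0.0323), over a range of p up to 1.0 with limma. In knockout RPE/choroid it passed with DESeq2 (log2 -0.787, adjusted p = 2.21e-04) and the rod term (log2 -0.749, adjusted p = 6.41e-04). Between knock-in and knockout RPE/choroid it passed in the fits named above, at log2 0.554, 0.636, 0.552 and 0.555.

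Of the 16, 11 and 16 lists that passed camera in retina, 1, 1 and 0 passed with an estimated correlation and 2, 1 and 3 with fry, which passed 3, 1 and 3 lists in all. In RPE/choroid 12, 12 and 14 lists fell to 0, 0 and 0 with either. Genes near Abca4 did not pass in knockout retina within 20 Mb or in knock-in retina within 5 Mb (odds ratio 1.51 and 12.4). By limma 2 genes differed between tissues in knock-in.

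With each library left out in turn, called genes ranged from 53 to 253, 15 to 29 and 103 to 202 in retina and from 22 to 462, 2 to 14 and 28 to 74 in RPE/choroid. Abca4 (log2) ranged from -0.396 to -0.236 in knock-in retina and, in RPE/choroid, from -0.93 to -0.534 in knockout and from -0.378 to 0.021 in knock-in. The last value, without wild-type library 2, has the opposite sign (adjusted p = 0.967). Lists ranged from 8 to 20 between knock-in and knockout RPE/choroid, and genes differing between tissues from 9 to 337, 2 to 10 and 7 to 42. In knock-in RPE/choroid, rod, cone and photoreceptor structure genes were higher by camera alone without wild-type library 2, as given above. Ribosomal proteins changed sign without wild-type library 0 (adjusted p = 0.585). Over the libraries left out, adjusted p ranged from 4.51e-11 to 0.0136 for rod, from 3.2e-07 to 0.0331 for cone, from 3.11e-10 to 0.091 for photoreceptor structure and from 1.47e-17 to 0.971 for ribosomal protein genes.

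Of 135 results of named genes, DESeq2 and RLE scaling kept all calls. The call was lost for 75 with limma on log2(FPKM + 1), 79 with log2(FPKM + 0.1), 93 with glmTreat, 30 with the sex term, 27 with the compared libraries alone, 27 with the table number as a block and at most 3 with other filters. The lens term ended 23 of 88 calls in retina. Where the sex term ended a call, log2 was 81.9% to 104% of the value without it and SE was larger in all 30. The share of higher genes in knock-in retina, 53.8%, became 30.0% and 27.3% with the limma settings and 1 of 5 with glmTreat. In knock-in RPE/choroid 5 of 10 became 69.8% with DESeq2 and 100% with limma on log2(FPKM + 0.1), glmTreat and the sex term, each with at most 2 genes.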

Other observations

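Without wild-type library 2, the RPE/choroid library with the most retinal transcripts, far more genes changed in knockout RPE/choroid, a comparison chosen after seeing the data. Of 15575 genes 462 changed (217 higher, 245 lower), including all 73 called with every library. Of 72 cytosolic ribosomal proteins 35 fell (median log2 -0.30, camera adjusted p = 7.36e-34, adjusted p = 0.366 with an estimated correlation). The complement list did not pass (1 of 19 risen, 4 fallen, camera adjusted p = 0.0866, and 0.366 with an estimated correlation). Of its members C1qa (56.8 to 39.4 FPKM, log2 -0.495, adjusted p = 0.0166), C1qb (log2 -0.36, adjusted p = 0.0423), C1qc (log2 -0.39, adjusted p = 0.0233) and Cfp (log2 -0.55, adjusted p = 0.0473) fell, while C4b rose (log2 0.80, adjusted p = 0.0454). Retinal lists were higher in the same fit, with rod (0 of 20 called, median log2 1.26, camera adjusted p = 1.58e-10), cone (median log2 1.42, adjusted p = 1.67e-04, with Arr3 and Gnb3 called of 11) and photoreceptor structure genes (1 of 23 called, median log2 1.30, adjusted p = 5.69e-12), each with adjusted p of 0.366 to 0.378 with an estimated correlation. The wild-type group held 2 libraries, with the lowest retinal shares of all (0.446% and 0.737%), so retinal content differs between these groups too.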
